A study of Mus musculus with 4 samples.

How the data were processed

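RNA of dissociated mouse cortex was profiled by scDART-seq, a single-cell method in which the cytidine deaminase APOBEC1 is fused to the m6A-binding YTH domain. The fusion converts cytosines next to N6-methyladenosine (m6A) to uracil, and the conversions are read as C-to-T changes in sequencing. Per the labels' protocols, mice were 6 to 8 weeks old when tamoxifen was first given, at 20 mg/kg every 24 h over 5 days, and tissue was taken 7 days after the last dose. Cortex was digested with papain, and the cells were fixed and barcoded in plates by repeated splitting and pooling with a kit of Parse Biosciences. The 4 samples are sublibraries 1 to 4 of a single pool, which held cells with APOBEC1-YTH and cells with APOBEC1-YTHmut, a version with a mutated YTH domain. The labels name replicates 1 and 2 as pooled in every sublibrary. The series text also describes sorted neuronal nuclei, and those libraries were not analysed here.

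A single site list covering the series was used. Per the submitters' processing notes, reads were aligned with STAR 2.7.5 and the genome build was mm10, and per the series text the sites of C-to-U conversion were found with the Bullseye pipeline. The authors deposited, for every site, its 1-base position, strand, gene symbol and a whole number, treated here as an unnormalized count and called the site count. The deposited list has no header, so what the count counts is not given in the sources used here. The number of cells in which a site was called is a possible reading, and the values below do not depend on it. Filters on cells, reads and sites, and the comparison with the mutant fusion, are not given in the sources used here. The list names no sample, genotype or cell type, so it was treated as 1 list with no replicates, and read depth per sublibrary is unknown.

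Sites were placed on the GENCODE M21 annotation, which has the coordinates of mm10, and coordinates are given 1-based. Of the 28412 sites, 27873 were matched to a gene by their symbol and strand, 391 through an older symbol and 105 by position only, and 43 had no annotated gene on their strand. Sequence was read from the annotated transcripts, so only exonic sites have a sequence context. As a check of build, strand and offset, 28337 of 28338 exonic sites had a C on their strand, and 28316 sites had a full context of 5 nt. Where transcripts of a gene differed, the region of a site was taken in the order 3' UTR, CDS, 5' UTR, noncoding exon, intron. Distances from the stop codon were measured along the longest coding transcript. RAC means the edited C preceded by A, with A or G before that, and DRACH means RAC with A, G or T before it and A, C or T after it.

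Shares were given with 95% bootstrap intervals from resampling genes 1000 times, because sites of a gene are not independent. Each share was set beside 1000 sets of random cytosines, 1 per site, from the exons of the same gene or, for motifs, of the same gene and region. Ratios of observed to expected contexts used RAC cytosines of the same gene and region, with genes resampled. The random cytosines carry no read depth, since depth is not in the list. The intervals cover the spread between genes within this list and not the spread between animals. No p-value was computed, because sites and genes of a list are not replicates.

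Before the data were examined, 20 gene lists were fixed, holding 347 different symbols. Symbols absent from the annotation, 2 among the oxidative phosphorylation genes and 1 among the cytoskeleton genes, are other names of genes in the same list and were not counted as members. They cover markers of excitatory neurons, inhibitory neurons, astrocytes, oligodendrocytes, oligodendrocyte precursors, microglia, endothelial and mural cells, and blood, ependyma and choroid plexus. The others cover presynaptic and postsynaptic genes, ion channels, immediate early genes, the m6A machinery, ribosomal proteins, nuclear-encoded oxidative phosphorylation genes, mitochondrially encoded genes, neurodegeneration genes, nuclear long noncoding RNAs, cytoskeleton and transport genes, and cell stress genes. For each list with at least 3 members in the data, the median number of sites per member with a site was placed among 10000 random lists of the same size. These were drawn from genes with a site and matched in 10 bins of exon length. They were not matched on expression, which is not in the list. A list was said to stand apart above the 97.5th percentile or below the 2.5th, as a description of this list of sites. The genes named in the text were also set beforehand: the 10 genes with the most sites, the genes of the 10 sites with the highest count, up to 3 members per gene list with the most sites, and Actb, whose 3' UTR holds a known m6A site. Some genes that this rule names are not reported here. Any other gene named was chosen after its values were seen.

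The scripts were tested on simulated data. For the DRACH share, with sites simulated in 4200 genes, 58 of 60 intervals held the true share. Of the simulated lists, 0 of 20 without enrichment and 40 of 40 with enrichment lay above all random sets. Sites were drawn independently within each gene, so clustering of sites was not simulated. The region shares used the same calculation and were not simulated. For the gene lists, with 4206 genes and 15 genes per list, 1 of 100 random lists fell outside the 2.5th to 97.5th percentiles, and 84 of 100 lists with 4 times the sites per gene lay above the upper one. Simulated exon lengths were unrelated to site numbers and members were picked at random. Matching on length and differences in expression were therefore not tested. Alternatives were merging sites within 10 nt, keeping only sites with a count at or above the median, 1 site per gene, another choice of transcript, a stop codon window of 200 nt, RAC in place of DRACH, and other matching of the gene lists. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.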

Results

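The site list of young mouse cortex held 28412 sites of C-to-U editing under 4206 gene symbols. It came from 4 sublibraries of a single cell pool, which mixed cells with the APOBEC1-YTH fusion and cells with its YTH-mutant control. As the list gives no sample, genotype or cell type, the comparisons are between sites, regions and genes within it, with no replicates. The sites were spread evenly over the strands, with 14283 on the plus strand and 14129 on the minus strand. Chromosome 2 held the most sites, 2817, and the Y chromosome 20. No site lay on the mitochondrial chromosome. The site count, an unlabelled whole number per site, ranged from 3 to 3538 with a median of 4 and a 90th percentile of 23, and 565 sites had a count of 100 or more.

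The bases around the edited cytosines were examined first. All 16692 exonic sites with a full sequence context and a count of 4 or more lay in RAC, and 0 lay outside it. Filters on sites are not given, and a filter may have made this edge. The RAC share at these counts is therefore no test of the m6A consensus. A further 22 exonic sites, 12 of them with a count of 4 or more, had no full context and were not classed. Among the 11624 sites with context and a count of 3, 5328 lay in RAC and 6296 did not. The RAC share at a count of 3 was 45.8% (95% interval 44.0 to 47.8), above all 1000 sets of random cytosines from the same genes and regions, which ranged from 11.5% to 13.3%. Of the sites outside RAC, 1812 had an A before the C without a purine before that A, and 4484 had another base before the C. A count of 3 was the lowest in the list and was carried by 11663 sites, or 41.1% of all.

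**Figure D1:**
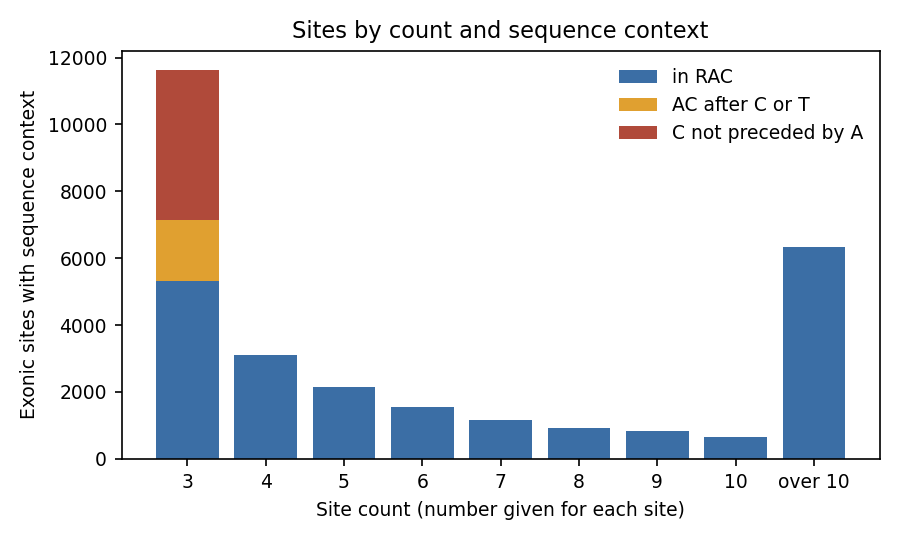
Number of exonic sites with sequence context (vertical axis) at each site count (horizontal axis, the whole number given per site), stacked by the bases before the edited C. The 6296 sites outside RAC are all in the bar at a count of 3, beside 5328 RAC sites, and the bars from 4 upwards hold RAC sites only.

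The 3' UTR held most sites. It contained 17599 sites, 61.9% of the list (95% interval 58.9 to 64.8), while coding sequence (CDS) held 7400 sites, 26.1% (24.0 to 28.0), and the 5' UTR 568 sites, 1.999% (1.67 to 2.34). Exons of noncoding transcripts held 2771 sites, or 9.75% (7.04 to 13.4), introns 31 and places outside annotated genes 43. Among exonic sites with sequence context, the 3' UTR share of 62.1% lay above all 1000 sets of random cytosines of the same genes, which gave 37.2% to 38.9%. The CDS share of 26.1% lay below them (28.6% to 30.0%), as did the 5' UTR share of 2.01% (8.63% to 9.66%). Noncoding exons also lay below, with 9.73% against 23.05% to 24.21%. Genes with noncoding exons only count the same on both sides, so this difference comes from noncoding transcripts of genes that also have coding ones. It does not describe long noncoding RNA genes. The random cytosines come from all annotated transcripts of a gene, whether expressed or not, which also lowers the random shares of the other regions. For RAC sites with a count of 4 or more, set against random RAC cytosines, the 3' UTR share was 64.3% (61.34 to 67.03) against 39.2% to 41.5%. Sites outside RAC had a 3' UTR share of 62.4% (58.2 to 66.8), against 35.1% to 38.6% of random cytosines outside RAC. RAC sites with a count of 3 had 54.99% (52.8 to 57.1) in the 3' UTR and 34.5% (32.5 to 36.4) in the CDS. On the longest coding transcript alone the 3' UTR held 64.4% against 44.5% to 46.4% in random sets, and the CDS 33.5% against 44.4% to 46.3%.

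**Figure D2:**
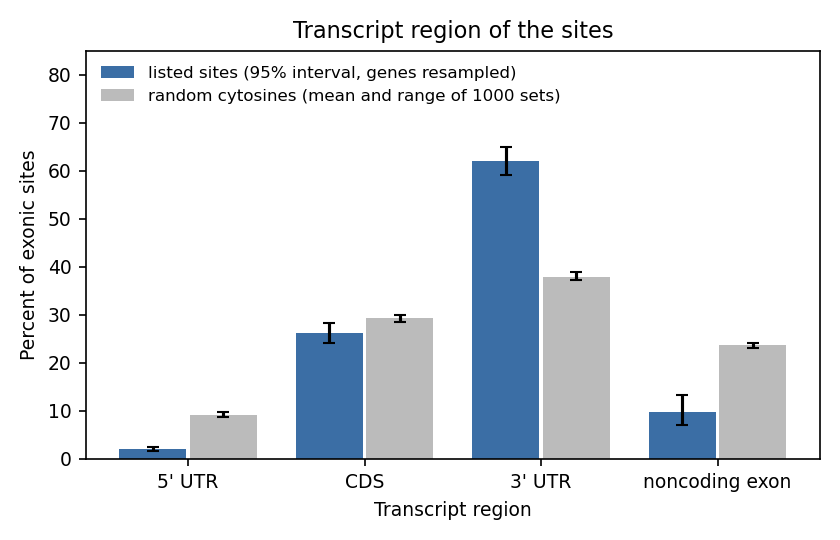
Percent of exonic sites (vertical axis) in each transcript region (horizontal axis). Blue bars are the listed sites with 95% intervals from resampled genes, and grey bars are random cytosines of the same genes, with the mean and the whole range of 1000 sets. The 3' UTR holds 62.1% of the sites and at most 38.9% of a random set.

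Sites gathered just after the stop codon. Of the 24707 sites on the longest coding transcript of 3591 genes, 30.3% (95% interval 29.0 to 31.8) lay within 400 nt of the stop codon, against 17.4% to 19.0% in random sets. Within 200 nt the share was 18.0% (16.9 to 19.3), against 8.95% to 10.1%. For RAC sites with a count of 4 or more the share within 400 nt was 30.9% (29.4 to 32.4), against 18.4% to 20.2% of random RAC cytosines. Sites outside RAC had 32.1% (29.9 to 34.4), against 17.2% to 20.4% of random cytosines outside RAC. The excess was thus not particular to RAC sites, and the random sets carry no read depth. The median site lay 229 nt after the stop codon. The bin from 0 to 200 nt after it held 1948 RAC sites with a count of 4 or more, where an even draw over the RAC cytosines of the same transcripts gave 686.7. The 200 nt before the stop codon held 718 such sites, where that draw gave 783.1, so the excess lay on the 3' UTR side.

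**Figure D3:**
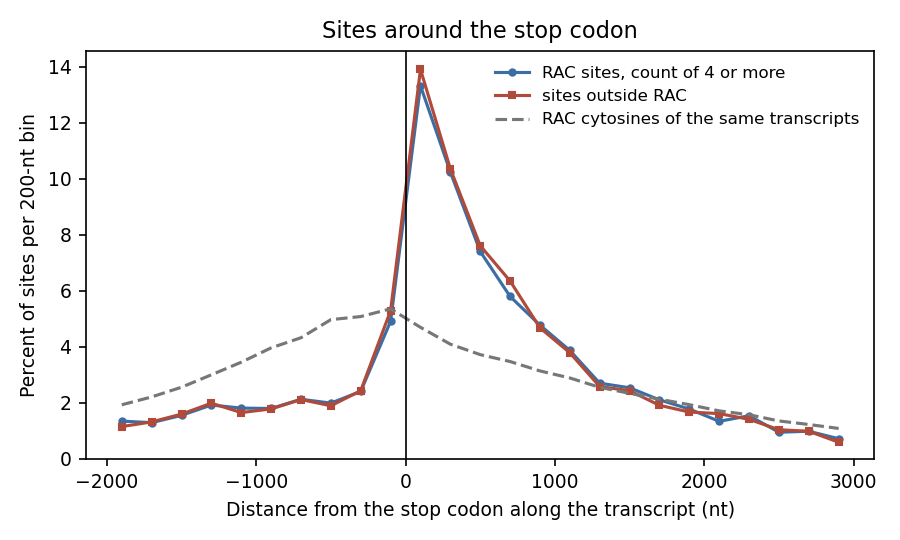
Percent of sites per 200-nt bin (vertical axis) by distance from the stop codon along the longest coding transcript (horizontal axis, nt, negative before the stop codon). Blue circles are RAC sites with a count of 4 or more, red squares sites outside RAC, and the dashed line all RAC cytosines of the same transcripts. Both kinds of sites peak in the bin after the stop codon.

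The DRACH motif was common among the sites. Of the sites with context, 55.2% (95% interval 54.5 to 56.0) lay in DRACH, against 8.96% to 10.3% of random cytosines of the same genes and regions. Among RAC sites with a count of 4 or more the comparison turned: 72.1% (71.2 to 72.9) were DRACH, against 76.1% to 78.4% of random RAC cytosines. At a count of 100 or more the share was 73.8% (68.4 to 77.8), inside the random range of 71.3% to 83.03% but at percentile 1.2. In noncoding exons, RAC sites of any count had 78.6% (76.1 to 80.7), also inside the random range (78.1% to 83.1%), at percentile 1.45. Both shares thus lay low among the random sets, in the same direction as the whole. The DRACH share of RAC sites was 77.0% (76.2 to 77.8) in the 3' UTR, where random RAC cytosines gave 79.2% to 81.5%, and 55.7% (53.9 to 57.3) in the CDS, where they gave 67.7% to 71.4%. The motif share at a count of 4 or more describes a list that holds RAC sites only. The 55.2% over all sites includes those sites, so its excess over random cytosines partly describes the same edge.

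Within RAC, contexts differed in how often they were listed with a count of 4 or more. GAACG was found 2.53 times as often as among random RAC cytosines (95% interval 2.34 to 2.75) and AAACG 1.88 times (1.71 to 2.06), both outside DRACH because of the G after the edited C. RAC contexts with that G had a ratio of 1.34 (1.26 to 1.42) in the 3' UTR and 2.18 (2.07 to 2.29) in the CDS. AAACA, the commonest context with 2407 sites, reached 1.78 times (1.71 to 1.85). At the other end, GGACC was found 0.325 times as often (0.275 to 0.378) and GGACT, often named as the favoured m6A motif, 0.485 times (0.418 to 0.553). The 4 bases GGAC together had a ratio of 0.515 (0.479 to 0.550). The median site count was 9 at GGACT, 7 at GGACC and 8 at GAACG, AAACG and AAACA.

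**Figure D4:**
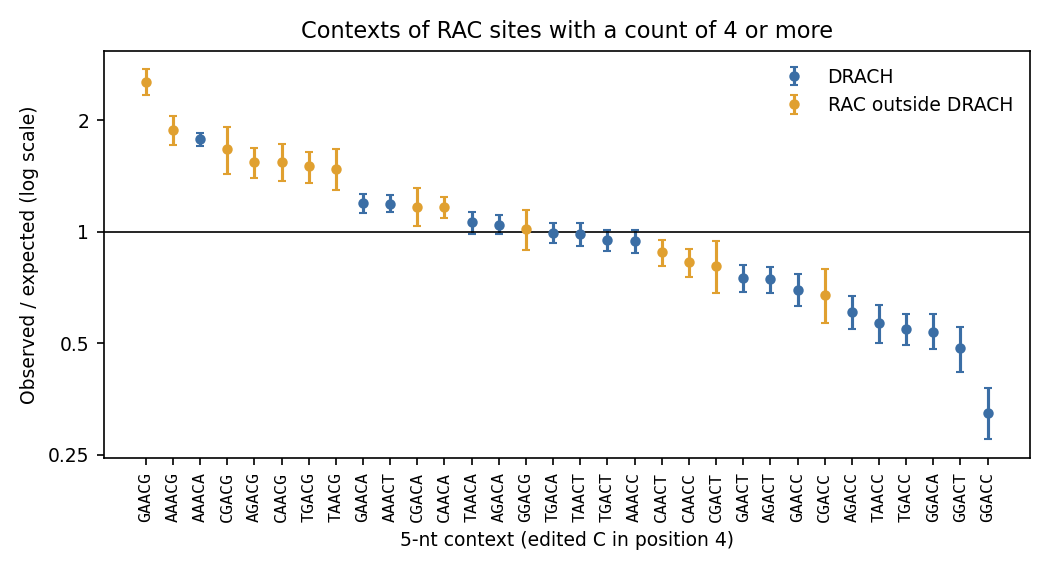
Observed over expected frequency (vertical axis, log scale) of each 5-nt context (horizontal axis, edited C in position 4) among RAC sites with a count of 4 or more. Points are ratios, bars 95% intervals from resampled genes, and the line marks a ratio of 1. The ratios run from 2.53 for GAACG to 0.325 for GGACC.

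Site counts differed little between regions. The median count was 5 at 3' UTR sites and 4 at CDS sites, a difference of 1 with a 95% interval from 0 to 1. Among RAC sites alone the medians were 6 and 5, with an interval of the difference from 1 to 2, which fell to 0 when 1 site per gene was kept. DRACH sites had a median count of 6 and other sites 3, and among RAC sites the medians were 6 and 5 (interval of the difference 0 to 1). As sites outside RAC have a count of 3 only, the larger of these differences describes that boundary of the list.

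Sites were concentrated in a small set of genes. The median gene had 2 sites and 1551 genes had 1, while 709 genes had 10 or more and together held 67.1% of all sites. Meg3, an imprinted long noncoding RNA, had the most, 356 sites, all in noncoding exons on chromosome 12 between 109541007 and 109571722. Malat1, a nuclear long noncoding RNA, followed with 256. Slc1a2, the main glutamate transporter of astrocytes, had 251 sites, of which 227 lay in its 3' UTR. Map1b, a microtubule-associated protein, had 194, with 125 in the 3' UTR and 69 in the CDS. Snhg11, fixed among the long noncoding RNAs but annotated as protein-coding in GENCODE M21, had 160. Syt1, the calcium sensor of synaptic vesicles, had 139, and Xist, the RNA that silences an X chromosome, 137. Pclo, a scaffold of the presynaptic active zone, had 128 sites, and 127 of them were in its CDS. CT010467.1 had 103 and Grin2b, an NMDA receptor subunit, 97. Long genes offer more cytosines: per kb of exon, Malat1 had 36.7 sites, Meg3 19.7, Slc1a2 19.1 and Grin2b 3.90.

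The highest counts belonged to few transcripts. Of the 10 sites with the highest count, 7 lay in exons of Malat1, led by position 5802535 of chromosome 19 with a count of 3538 in the context AAACT. A further 2 carried the symbol CT010467.1, at 39846768 and 39846876 of chromosome 17, with counts of 2561 and 1209. That symbol is annotated as a ribosomal RNA gene on the minus strand from 39846353 to 39848827, while its 103 sites are listed on the plus strand. They are therefore not assigned to that annotated gene here. The strand alone does not exclude ribosomal RNA as the source of these reads, and their source was not determined. The last of the 10 was in the 3' UTR of Camk2n1, an inhibitor of CaMKII, at 138457652 of chromosome 4 with a count of 1099. Actb, named beforehand for its known m6A site in the 3' UTR, had 37 sites on chromosome 5, with 22 in the 3' UTR and 15 in the CDS. Its highest count, 581, was at 142903757, 41 nt after the stop codon, in the context TGACA. In the context GGACT, its 3' UTR sites had counts of 23, 6 nt after the stop codon, and 3, 266 nt after it. Which listed position is the known m6A site was not determined, so the highest count is not read as that site.

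Genes of synapses and excitatory neurons carried many sites. All 20 presynaptic genes of the fixed list had a site, with a median of 20.5 per gene, and so did all 20 postsynaptic genes, with a median of 21.5. No random list of genes with matched exon length reached either median (0 of 10000). Expression was not matched, because it is not in the list. High medians here and in the lists below may therefore come from deeper reads of abundant transcripts. Syt1 with 139 sites and Pclo with 128 led the presynaptic list, and Grin2b with 97, Gria2 with 95 and Camk2a with 81 the postsynaptic one. Of 18 markers of excitatory neurons 17 had a site, with a median of 12 that 0 of 10000 random lists reached. These lists share members such as Camk2a and Gria2 and are not independent. Of 18 ion channel genes 17 had a site, with a median of 14 (percentile 99.8), including the sodium channels Scn2a with 68 and Scn8a with 42. Of 15 markers of inhibitory neurons 6 had a site, with a median of 4.5 (percentile 76.0), among them Cnr1 with 8 and Gad2 with 7.

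Among glial and vascular markers the lists differed. Of 20 astrocyte markers 18 had a site, with a median of 14.5 that 0 of 10000 random lists reached. Slc1a2 led with 251, followed by Sparcl1 with 76 and Slc1a3 with 65. Of 18 endothelial and mural markers 14 had a site, with a median of 10 that 2 of 10000 random lists reached, led by the pericyte marker Rgs5 with 67. Of 19 oligodendrocyte markers 13 had a site, with a median of 4 (percentile 93.7), including Mal with 36 and Qk with 30. Of 10 markers of oligodendrocyte precursors 4 had a site, with a median of 9.5 (percentile 85.6), including Tnr with 20 and Ptprz1 with 17. Of 20 microglia markers 4 had a site, with a median of 1 (percentile 10.1): Sparc, which other brain cells also express, had 17, and Cx3cr1 and Csf1r had 1 each. Of 9 blood, ependyma and choroid plexus markers 3 had a site, with a median of 8 (percentile 96.6), namely Enpp2 with 19, Ttr with 8 and Ccdc153 with 1.

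Of the remaining lists, long noncoding RNAs and cytoskeleton genes had the highest medians, and ribosomal protein and oxidative phosphorylation genes the lowest. Of 11 nuclear long noncoding RNAs 10 had a site, with a median of 56.5, and of 22 cytoskeleton and transport genes 19 had a site, with a median of 20. Neither median was reached by any of 10000 random lists. Map1b with 194, Ank2 with 84 and Sptbn1 with 70 led the cytoskeleton list. Of 21 immediate early genes 14 had a site, with a median of 6 (percentile 99.8), led by Egr3 with 22. Of 21 neurodegeneration genes 16 had a site, with a median of 6.5 (percentile 98.6), led by App with 68, Prnp with 44 and Mapt with 20. Of 16 cell stress genes 9 had a site, with a median of 5 (percentile 97.1), led by Hsp90aa1 with 25. Of 20 genes of the m6A machinery 9 had a site, with a median of 5 (percentile 89.3). These included the reader Ythdf2 with 22 and the RNA-binding protein Hnrnpa2b1 with 25, while the methyltransferase genes Mettl3 and Mettl14 had 0. Of 25 ribosomal protein genes 3 had a site, among them Rpl4 with 4 and Rpl8 with 1, with a median of 1 (percentile 25.4). Of 21 nuclear-encoded oxidative phosphorylation genes 8 had a site, with a median of 1 (percentile 12.3) and a maximum of 3 in Cox8a. Of 15 mitochondrially encoded genes 0 had a site. Expression is not in the list, so a gene with no site may be unexpressed, too thinly read, not edited or removed by a filter, and ribosomal protein genes, which all cells use, had a site in 3 of 25 cases. The percentiles describe genes with a site only, and a high one may reflect expression as well. The calls of the immediate early and neurodegeneration lists were lost when only sites at or above the median count were kept (percentiles 95.4 and 92), and that of the neurodegeneration list also when sites within 10 nt were merged (percentile 94.5).

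**Figure D5:**
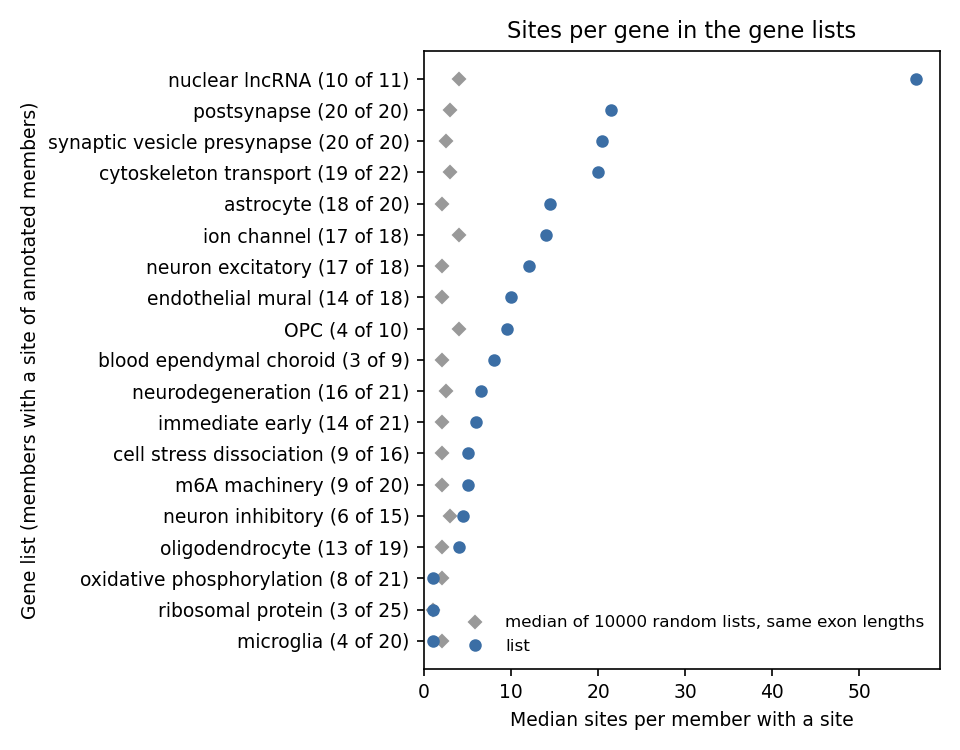
Median number of sites per member with a site (horizontal axis) for each gene list (vertical axis, with the members that had a site of all annotated members). Blue circles are the lists and grey diamonds the median of 10000 random lists of the same size and exon length. The list of nuclear long noncoding RNAs is highest at 56.5, and the microglia, ribosomal protein and oxidative phosphorylation lists are at 1.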

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

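Alternatives that put CDS before 3' UTR or kept RAC sites only were chosen after seeing the data, as were the random sets on the longest transcript. The 3' UTR share fell to 53.5% with 1 site per gene and to 57.9% with CDS before 3' UTR. The CDS share was 33.5% on the longest coding transcript, 30.0% with 1 site per gene and 30.1% with CDS before 3' UTR, and the 5' UTR share 2.69% with 1 site per gene. Against random cytosines under either other region rule, the 3' UTR share stayed above all 1000 sets and the CDS and 5' UTR shares below. A window of 200 nt gave 18.0% near the stop codon. The DRACH share was 77.8% with RAC in its place, 58.6% with 1 site per gene, 72.1% at or above the median count and 71.02% for RAC sites only; sites outside RAC drop out of the last pair. With 1 site per gene, the median count of RAC sites differed by 0 between 3' UTR and CDS. Between DRACH and other sites the median count then differed by 1 over all sites and by 0 among RAC sites. Sites at or above the median count numbered 16749. The most sites in a gene fell to 188 after merging sites within 10 nt and to 196 at or above the median count. Causes were not tested unless given. Of the gene list calls, immediate early genes fell to percentile 95.4 at or above the median count, and neurodegeneration genes to percentile 94.5 after merging and 92 at or above the median count. Oligodendrocyte markers rose to percentile 97.9 after merging, and cell stress genes to percentile 99.3 after merging and 97.6 matched on 3' UTR length. The other alternatives moved no call. Leaving out the mitochondrial chromosome moved nothing, as it held 0 sites. Cell types were not run, as the list names none, nor were ribosomal protein genes at or above the median count, with too few members. No paired analysis was possible because the list has no groups or replicates.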

Other observations

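Sites on both strands of the same place were listed at several genes, chosen here after their values were seen. Of all sites, 547 (1.93%) lay inside an exon of another listed gene on the opposite strand. Gm37376, which lies opposite Malat1, carried 39 such sites with a highest count of 735, and Cdr1, opposite C230004F18Rik, carried 38 with a highest count of 62. Celf5 had 19 sites opposite Gm16105, and Tsix had 3 opposite Xist. Of the 103 sites under CT010467.1, 68 lay in exons of Gm42418 and 35 had no annotated gene on the plus strand.

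The tests of a filter, of rare edits, of read depth around a site, of base composition and of both APOBEC1 preferences were chosen after their results, or values close to them, had been seen. The list holds a single group, so no biological explanation was tested against another group.

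Sites outside RAC ended at a count of 3: 0 of the 16692 sites with context and a count of 4 or more were outside it, so a filter that kept RAC sites only above 3 may have made this edge. Rare edits with no filter are argued against, since the upper limit (3 counts for a count of 0) was 0.04765 sites at a count of 4 per 100 at a count of 3, against 58.3 in RAC. Sites outside RAC lay within 20 nt of an RAC site with a count of 4 or more in 74.4% of cases, above random cytosines of the same gene and region (13.3% to 16.1%) and above unlisted cytosines within 100 nt (mean 39.3%, range 37.7% to 40.9%), which argues against depth of the gene or of the place alone. That share was 52.4 percentage points (50.3 to 54.2) higher than in RAC sites with a count of 3. This met the condition written beforehand for bystander edits, meaning edits beside an RAC site with a count of 4 or more. Sites outside RAC all had a count of 3, so any with a higher count that a filter removed are missing from this comparison. RAC sites with a count of 3 had 22.1%, against 3.44% to 4.94% of random unlisted RAC cytosines, so part of the gap may lie in the differing baselines. A site outside RAC lay within 10 nt of 9.18% of RAC sites with a count of 3 and of 65.9% of those above 100. Deeper reads at sites with a high count could give the same rise, so it does not decide on bystander edits. An A or T came before the C in 62.5% of sites outside RAC, against 41.8% to 45.7% at random. Most of this excess was A, with 28.8% against 11.86% to 14.98%, while T had 33.75% against 28.3% to 32.08%. The base preference of APOBEC1 may add to the edits outside RAC. However, 48.6% of these sites lay within 5 nt of an RAC site, and the random cytosines were not matched on nearby sequence.

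RAC sites lay near the stop codon more often than random RAC cytosines, and neither read depth along the transcript nor distance from exon junctions could be settled as the source. For depth, RAC sites with a count of 3 differed from sites outside RAC by -5.53 percentage points (-7.71 to -3.38) in the share within 400 nt, but sites outside RAC sit beside RAC sites (74.4% within 20 nt), so they are no independent control. Of CDS sites in RAC with a count of 4 or more, 60.2% lay within 100 nt of a junction, below all random sets (67.2% to 70.4%). They were 2.86 points (0.258 to 5.58) above the sites outside RAC, which met the condition written beforehand for setting junctions aside; that condition rested on the same control and was wrong for the same reason, a judgement made after the value was seen. In internal exons of 400 nt or more, 11.4% (8.93 to 14.4) of 1128 such sites lay within 100 nt of a junction. Random RAC cytosines of the same exons gave 13.0% to 18.6%, and the difference from their mean was -4.27 points (-6.35 to -2.02). This argues against a steady rise of depth towards the 3' end as the source of the distance from junctions. A drop of depth at exon ends would give the same values and could not be checked, since depth is not in the list. Both explanations of the stop codon pattern stay open.

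GGAC contexts were rarer and AAACA commoner among RAC sites than among random RAC cytosines. Base composition around the sites is argued against as the whole source, because against the other RAC cytosines within 100 nt the ratio was 0.588 (0.548 to 0.624) for GGAC and 1.23 (1.19 to 1.27) for AAACA, though the latter is nearer to 1 than the 1.78 found over the same gene and region. For GGAC, dilution by weak neighbours is argued against as well, since at sites with a count of 20 or more and no higher site within 50 nt the GGAC ratio was 0.375 (0.277 to 0.479). At sites not preceded by A, 5 of 5 flanking base shares lay beyond all random sets in the same direction as at RAC sites, for example G after the C in 17.1% against 7.29% to 9.66%. A preference of APOBEC1 for flanking bases is therefore a candidate explanation, though many of these sites lie beside RAC sites and share their surroundings.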
